A study of Homo sapiens with 24 samples.

How the data were processed

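PolyA RNA from the human osteosarcoma cell line U2OS was measured in 24 libraries: 4 genotypes at 0, 4 and 8 h, with 2 libraries in each of 12 groups. The genotypes were control cells with an empty vector (sgNS+EV), QKI-targeted cells with an empty vector (sgQKI+EV), and QKI-targeted cells given back QKI7 either intact (QKI7-WT) or, by its label, without the KH domain (QKI7-dKH). The chase combined actinomycin D (5 µg/mL) with sodium arsenite (200 µM) for the stated times. Groups were taken from the sample titles.

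One table was used, with 12585 rows and 1 column per library. It held 38 ERCC spike-in rows and 12547 endogenous rows keyed by gene symbol. The deposited values are a signal on a linear scale that the authors had normalised to the ERCC spike-in RNAs. That reading rests on the values: the ERCC rows summed to between 11485 and 11940 in every library, while the endogenous rows summed to between 690400 and 1368000 and fell with time. The unit before the spike-in step, and whether it used 1 factor per library or a curve, were not given in the sources used here. Nor was it given how or when the spike-in was added, per cell or per amount of RNA, so a difference that is shared by most genes has no known per-cell meaning. The submitters' processing notes name STAR, RSEM and GRCh38 without versions. The lowest value was 0.641 and 731 values were below 1. 38 rows were identical to an earlier row. Read counts are not in the table, so the depth of each library is unknown and no counting error could be given. Precision was therefore taken from replicate libraries, whose log2 values correlated with Pearson r between 0.9889 and 0.9982 across genes, which are not independent replicates. The median standard error (SE) of a difference between groups was 0.11 log2, and 0.15 for a difference in decay.

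Values were analysed as deposited, as log2 of the value plus 1. A filter of at least 1 in at least 2 libraries removed no gene. A linear model with 12 group means was fitted to all 24 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend. It left 12 residual degrees of freedom and a prior of 9. P-values were adjusted by the Benjamini-Hochberg method over 12547 genes, with a threshold of 0.05, and all tests were two-sided. A gene past the threshold is said to have passed, or to have been higher, lower, risen or fallen. Log2 changes and folds come from this fit, so they are of values plus 1 and differ from ratios of printed means. Standard deviations (SD) come from the 2 libraries of a group.

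The comparisons were genotype differences at 0 h, the change from 0 h to 8 h in each genotype, and decay differences. A decay difference is the change from 0 h to 8 h in 1 genotype minus that in another, tested as an interaction. A negative value means a larger fall in the first genotype. 5 comparisons are treated in full: sgQKI+EV against sgNS+EV and QKI7-WT against QKI7-dKH at 0 h, the 8 h change in sgNS+EV, and both matching decay differences. Half-lives assume exponential loss between the 0 h and 8 h group means, without the added constant, while arsenite was present.

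32 gene lists were tested, of which 29 had at least 5 measured members. Metallothioneins and zinc export had 4 measured members, hepatocyte markers 1, and mitochondrially encoded mRNAs 0. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. The fry test was run beside it. Its first p-value asks whether a list's genes move 1 way on balance and its mixed p-value whether they change in either direction; neither compares a list with other genes. Counts of members are given over all genes and with p-values adjusted over the list alone. Of the table's symbols, 11726 are current, 605 were matched as older symbols and 216 were not matched. Positions are on GRCh38 from GENCODE 29.

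Groups, comparisons, tests, thresholds, gene lists, the naming rule and most alternative settings were fixed before the data were examined. The plan assumed values relative to the library total, since no spike-in was named in the labels. The spike-in scaling of the deposited values was kept as the main scale, and scaling to library totals was run as an alternative. Named genes are QKI, METTL1, WDR4 and G3BP1. For each of the 5 main comparisons they are also the 8 highest and 8 lowest changes among genes that passed, with a mean signal of at least 1 and the same direction in both replicates. Up to 4 members that passed in each list, and 3 genes per direction in other comparisons, were added. Genes named outside this rule are said to be so.

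Alternatives were quantile normalisation, library totals, a pseudocount of 0.1, no filter, a replicate term, a fit on the compared groups alone, 4 h in place of 8 h, a fold limit of 2 (1.5 for decay differences) and leaving out each library in turn. 3 alternatives were added after the data were seen. They are library totals without ribosomal RNA, a spike-in axis as a covariate, and a fit without the 4 h libraries. The spike-in axis is the first principal component of the log2 values of 19 ERCC rows with a mean of at least 20, and carried 80.2% of their variance. It rests mainly on ERCC-00060 (loading 0.783, mean 38.17), followed by ERCC-00003 (0.389). Methods that need counts could not be used.

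The procedure was tested on simulated data with 200 changed genes among 12547. At a log2 change of 1 it recovered 100% of changed genes for sgQKI+EV against sgNS+EV at 0 h and 91% for the matching decay difference. At 0.5 it recovered 58.2% and 41.8%. False calls were 4.97% and 7.19% of the calls, the second above the nominal 5%. For the decay difference between QKI7-WT and QKI7-dKH it recovered 53.7%, 82.1% and 97% at 0.5, 1 and 2. A list of mitotic genes shifted by −0.3 was called in 20 of 20 simulations, and an unshifted one in 0 of 20. The simulated genes varied independently of each other. These runs therefore do not show how often a list of correlated genes would be called falsely. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

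The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.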

Results

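U2OS cells, a human osteosarcoma line, were profiled as polyA RNA in 24 libraries. They span 4 genotypes and 3 time points of a chase with actinomycin D, which blocks transcription, and sodium arsenite, an oxidative stressor. Each of the 12 groups had 2 libraries. The series asks how QKI, a STAR-family RNA-binding protein, affects mRNA stability. Control cells carried the sgNS guide and an empty vector (sgNS+EV), and targeted cells a QKI guide and an empty vector (sgQKI+EV). The add-back cells carried the QKI guide with intact QKI7 (QKI7-WT) or with QKI7 lacking the KH domain (QKI7-dKH), the part that contacts RNA. Values are the deposited spike-in-normalised signal of 12547 genes. Read depth is unknown, and the endogenous signal summed to between 690400 and 1368000 per library. Group values below are means ± SD with n = 2, and changes are log2 with the SE of the limma fit.

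QKI (chromosome 6, 163414000 to 163578596) was lower in targeted cells at every time. At 0 h its signal was 59.98 and 48.19 in the sgNS+EV libraries, 35.98 and 32.66 in sgQKI+EV, 60.43 and 46.28 in QKI7-WT, and 47.55 and 50.17 in QKI7-dKH. At 4 h the same genotypes gave 53.97 and 50.09, then 15.35 and 17.14, then 50.53 and 32.8, then 24.75 and 22.6. At 8 h they gave 24.05 and 21.95, then 10.61 and 11.67, then 18.7 and 17.97, then 17.83 and 19.05. In sgQKI+EV the 0 h level was 0.644 of control (−0.63, SE 0.14, adjusted p = 0.0264), and the 8 h level differed by −0.98 (adjusted p = 9.51e-05). Against sgQKI+EV at 0 h, QKI was higher in QKI7-dKH by 0.50 (adjusted p = 0.0339), while the difference in QKI7-WT, 0.61, did not pass (adjusted p = 0.142). That difference did pass with the spike-in axis as a covariate (0.70, adjusted p = 1.25e-06), from the compared groups alone (3.45e-05) and without the 4 h libraries (0.0291). The difference between QKI7-WT and QKI7-dKH at 0 h, 0.11, did not pass either (adjusted p = 0.587). The 0 h call in sgQKI+EV was lost with library totals (−0.46, adjusted p = 0.0781; 0.0987 without ribosomal RNA). It was also lost without sgNS+EV replicate 1 (0.3) and without sgQKI+EV replicate 1 (0.0777) or 2 (0.357). The call in QKI7-dKH was lost without any 1 of the 4 libraries (0.0795 to 0.254) and with each other scaling (0.551 to 0.873). The row is per gene, so transcript from the edited locus and from the add-back construct cannot be separated. QKI fell from 0 h to 8 h by 1.19 in sgNS+EV, by 1.54 in sgQKI+EV, by 1.36 in QKI7-dKH and by 1.48 in QKI7-WT.

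**Figure D1:**
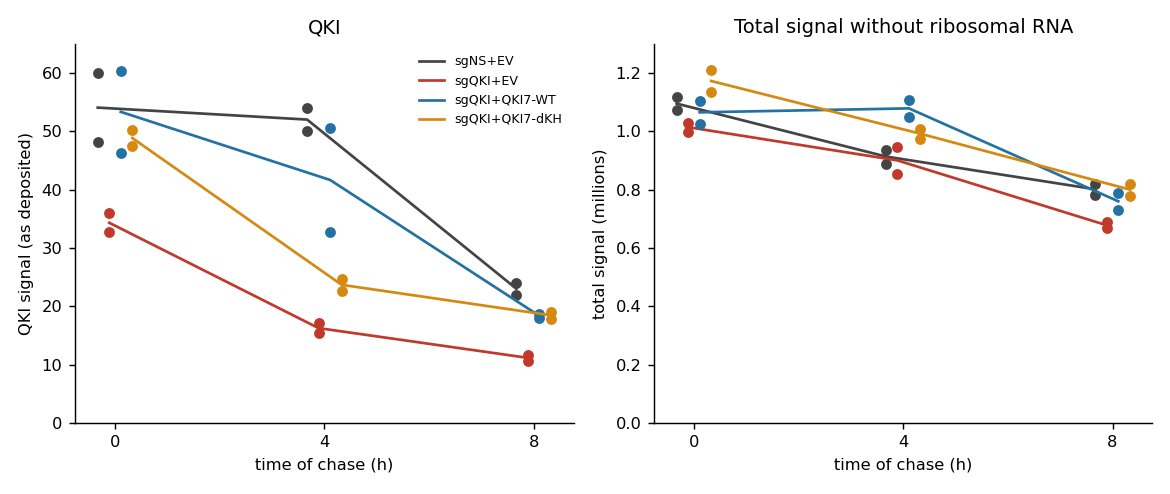
QKI signal (left) and total signal without ribosomal RNA (right, divided as its axis states) against hours of chase in the 4 genotypes, with 1 point per library and lines through group means. QKI was lowest in sgQKI+EV at each time, and the mean total at 8 h was 677800 in sgQKI+EV and 801400 in sgNS+EV.

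Total signal without ribosomal RNA, a scale set by the spike-in, was lower at 8 h than at 0 h in each genotype. It went from 1096000 ± 31800 at 0 h to 913800 ± 33900 at 4 h and 801400 ± 27700 at 8 h in sgNS+EV. In sgQKI+EV it went from 1014000 ± 21900 to 900400 ± 66700 and 677800 ± 14600, and in QKI7-dKH from 1173000 ± 53700 to 992000 ± 24000 and 800400 ± 29300. In QKI7-WT it was 1066000 ± 54400 at 0 h, 1079000 ± 41000 at 4 h and 760200 ± 42300 at 8 h. Ribosomal RNA took 10% of the endogenous signal in sgNS+EV at 0 h, and 5.88% in sgQKI+EV, 8.23% in QKI7-WT and 8.65% in QKI7-dKH. The QKI7-WT libraries at 4 h stood apart from each other, with r = 0.9889 across genes, the lowest of the 12 groups.

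The first comparison asked which transcripts differed in QKI-targeted cells before the chase. SYNGR1, a synaptic vesicle protein gene (chromosome 22, 39349925 to 39385588), was 2.08-fold higher, from 14.9 ± 0.51 to 32.1 ± 1.9 (1.06, SE 0.10, adjusted p = 3.51e-06). FLVCR1, a heme and choline transporter gene (chromosome 1, 212858255 to 212899363), went from 5.54 ± 0.16 to 11.9 ± 2.2 (0.97, SE 0.12). PTBP2, the neuronal polypyrimidine-tract splicing regulator (chromosome 1, 96721665 to 96823738), went from 29.1 ± 0.83 to 53.5 ± 0.91 (0.86, SE 0.12). COL3A1, a fibrillar collagen (chromosome 2, 188974320 to 189012746), fell from 52.5 ± 0.99 to 26.3 ± 0.11 (−0.97, SE 0.07, adjusted p = 1.45e-07). In all, 195 genes passed, 23 higher and 172 lower, and 5 of them changed at least 2-fold.

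Other genes at the upper end were FLJ23867 at 0.94, KISS1 at 0.84, CKMT1B at 0.77, CD180 at 0.74 and NID1, a basement membrane protein gene, at 0.63. At the lower end were the small nucleolar RNA SNORD17 at −1.51 (SE 0.34), POP3 at −1.39 and the TNF receptor adaptor TRADD at −1.10. PCAT6 and L3HYPDH at −0.95 and IGFL3 at −0.94 followed. Across 37 small RNA rows, of which SNORD17 alone passed, the median was −1.28. The SNORD17 value thus lay near the median of its class. METTL1 and WDR4, the subunits of an m7G methyltransferase, and G3BP1, a stress granule nucleator, gave −0.06, 0.18 and 0.06, with adjusted p of 0.914, 0.571 and 0.789.

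Several lists held genes that passed. Of 36 extracellular matrix and mesenchymal genes 3 fell, COL3A1, the small proteoglycan gene LUM (−0.70) and fibronectin FN1 (−0.32), and none rose. Of 32 NRF2 targets, the antioxidant response genes, OSGIN1 (0.45), TRIM16 (0.38) and TXNRD1 (0.29) rose and none fell. Both nuclear long non-coding RNAs NEAT1 (−0.48, adjusted p = 9.01e-05) and MALAT1 (−0.51) fell among 6 measured. In the integrated stress response list of 29 genes, DDIT4 (−0.51) and GDF15 (−0.75) fell and MTHFD2 (0.29) rose; GDF15 was also the 1 of 28 p53 targets that fell. Single members that fell were JUNB (−0.47) of 33 immediate-early and ARE-containing mRNAs, CRYAB (−0.38) of 30 heat shock genes, UBE2L6 (−0.37) of 30 interferon-stimulated genes, ALDOC (−0.47) of 20 glycolysis genes and SNHG16 (−0.31) of 21 snoRNA host genes. Single members that rose were HIST1H2BK (0.37) of 17 replication-dependent histones, PTBP2 of 38 SR proteins and hnRNPs, and H2AFY (0.37), a macroH2A histone gene, of 13 genes with a published link to QKI. Of 351 zinc finger genes named ZNF 3 fell: ZNF581 (−0.53), ZNF32 (−0.41) and ZNF395 (−0.32).

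No member passed over all genes among 75 cytosolic ribosomal protein mRNAs, yet 27 were lower with p-values adjusted over the list alone, and their median of −0.22 lay below that of all genes (difference −0.16, camera adjusted p = 1.58e-17; adjusted p = 0.913 with an estimated correlation). That difference was −0.04 with quantile normalisation. Adjusted over the list alone, the matrix list gave 0 higher and 7 lower, NRF2 targets 4 and 2, interferon-stimulated genes 0 and 7, snoRNA host genes 0 and 7, long non-coding RNAs 0 and 3, the stress response list 2 and 3, QKI-linked genes 2 and 4, immediate-early mRNAs 1 and 2, histones 1 and 1, YAP and TAZ targets 1 and 0, and ZNF genes 0 and 2. SR proteins and hnRNPs gave 1 higher, and p53 targets, heat shock genes, glycolysis and osteoblast-lineage genes 1 lower each. None passed, over all genes or over the list alone, among 76 respiratory chain, 60 mRNA decay, 50 stress granule, 46 Hippo pathway, 44 DNA replication, 37 mitotic, 31 proteasome, 24 cholesterol biosynthesis, 22 unfolded protein response and 18 m7G and cap genes, 4 metallothioneins, 5 blood cell and 7 epithelial markers, and 1 hepatocyte marker. Over all genes none passed among 24 YAP and TAZ targets or 7 osteoblast-lineage genes.

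Camera placed 7 lists below other genes: ribosomal proteins, interferon-stimulated genes (0.00454), respiratory chain (0.0059), matrix (0.00773), snoRNA hosts (0.0125), long non-coding RNAs (0.0224) and p53 targets (0.0303). It placed 8 above: YAP and TAZ targets (0.00454), NRF2 targets (0.00629), DNA replication (0.00953), mitotic, proteasome and SR protein genes (0.0155 each), histones (0.0162) and heat shock genes (0.0303), whose only member that passed, CRYAB, fell. For each of these 15 calls adjusted p = 0.913 with an estimated correlation, so none held. The other lists gave 0.141 for blood cell markers, 0.167 for glycolysis, 0.199 for Hippo, 0.426 for immediate-early mRNAs, 0.592 for the stress response, 0.651 for cholesterol, 0.683 for QKI-linked genes, 0.751 for mRNA decay, 0.84 for ZNF genes and 0.843 for the remaining 5. Median and test differed in sign for the stress response, cholesterol and ZNF lists, and median and mean for mitotic, DNA replication and histone genes.

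The median of all genes was −0.06 here (−0.106 to −0.013 with 1 library left out), and scaling to library totals moved it to 0.106; with that scaling 930 genes were higher and 102 lower, and with quantile normalisation 325 and 451. The named genes that passed kept their direction under each scaling. The count was 40 without sgNS+EV replicate 1, 39 without its replicate 2, 99 without sgQKI+EV replicate 1 and 25 without its replicate 2. Of 37 named genes that passed, 8 passed whichever library was left out, among them SYNGR1, FLVCR1, FLJ23867, PTBP2, NID1, COL3A1 and NEAT1.

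The second comparison asked which transcripts differed before the chase between cells given intact QKI7 and cells given QKI7 without the KH domain. SUGCT, a mitochondrial glutarate CoA-transferase gene (chromosome 7, 40134977 to 40860763), was 11.2 ± 1.0 in QKI7-WT and 24.2 ± 0.22 in QKI7-dKH, a fold of 0.483 (−1.05, SE 0.11, adjusted p = 2.97e-05). It was 14.1 ± 0.95 in sgNS+EV and 15.4 ± 1.4 in sgQKI+EV. HMGCS1, the HMG-CoA synthase of the mevalonate pathway (chromosome 5, 43289395 to 43313512), was 85.6 ± 3.3 against 121 ± 2.8 (−0.49, SE 0.06, adjusted p = 1e-04). Its level was 78.6 ± 0.68 in sgNS+EV and 86.7 ± 2.1 in sgQKI+EV. COL3A1 was higher in QKI7-WT, 27.3 ± 0.3 against 21.2 ± 0.91 (0.35, SE 0.07). In all, 471 genes passed, 6 higher and 465 lower in QKI7-WT, and 3 differed at least 2-fold.

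Other higher genes were TMSB15B at 0.52, the matrix protease MMP7 at 0.45, the serine protease HTRA1 at 0.29 and FHL1, a LIM-domain protein gene, at 0.25. Lower genes included MFAP5, a microfibril protein gene, at −1.01, SERPINB7 at −1.0, MYL2, a myosin light chain gene, at −0.96, CASC8 at −0.93, LOC100507424 at −0.88, VAMP8 at −0.86 and ABCC6P2 at −0.83. METTL1, WDR4 and G3BP1 gave −0.13, −0.11 and −0.20, with adjusted p of 0.497, 0.518 and 0.0886.

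In cholesterol biosynthesis 12 of 24 genes were lower and none higher, and 19 were lower adjusted over the list alone. HMGCS1, DHCR7 (−0.43), ACAT2 (−0.43) and MSMO1 (−0.41) were among them, and the list's median of −0.35 lay below that of all genes (difference −0.20, camera adjusted p = 5.54e-11). The call was lost, at adjusted p = 0.31 with an estimated correlation. Of 36 matrix genes 13 were lower, such as THBS1 (−0.60), COL11A1 (−0.42), LAMB1 (−0.40) and FN1 (−0.40), and COL3A1 was higher; over the list alone 24 were lower and 2 higher. Of 24 YAP and TAZ targets 6 were lower, such as MYOF (−0.42), ANKRD1 (−0.37) and CTGF (−0.34), and 16 over the list alone. Of 46 Hippo pathway genes 5 were lower, such as FAT1 (−0.36), YAP1 (−0.34), AMOTL2 (−0.30) and TEAD1 (−0.28), and 9 over the list alone. Of 28 p53 targets 5 were lower, such as RRM2B (−0.51), RPS27L (−0.34) and CCNG1 (−0.31), and 15 over the list alone. Of 22 unfolded protein response genes 6 were lower, such as PDIA4 (−0.35), CALR (−0.33) and EDEM1 (−0.31), and 13 over the list alone.

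In smaller numbers, lower genes were IFI6 (−0.51) with 3 others of 30 interferon-stimulated genes, and PSMC6 (−0.26) with 3 others of 31 proteasome subunits. Of 33 immediate-early mRNAs 3 were lower, such as LIF (−0.49). Of 30 heat shock genes 3 were lower: HSPB8 (−0.30), HSPH1 (−0.25) and DNAJA1 (−0.24). Of 38 SR proteins and hnRNPs PTBP2 (−0.58), SRSF1 (−0.26) and SRSF3 (−0.22) were lower, and of 17 histones HIST1H4H (−0.47), HIST1H1C (−0.45) and HIST1H2BK (−0.30). MT1E (−0.43) and SLC30A1 (−0.29) were lower among 4 metallothionein and zinc export genes, and ZNF114 (−0.49) and ZNF404 (−0.35) among 351 ZNF genes. Single lower members were TNFRSF11B (−0.74) of the osteoblast list, PCNA (−0.25) of DNA replication, EIF4G2 (−0.28) of stress granule proteins, CNOT11 (−0.29) of mRNA decay, SDHD (−0.32) of the respiratory chain, CCND1 (−0.32) of the QKI-linked genes and SERPINA1 (−0.29), the hepatocyte marker. Over the list alone the lower members numbered 6 for interferon-stimulated genes, 10 for proteasome, 3 for immediate-early mRNAs, 13 for heat shock, 13 for SR proteins, 4 for histones, 4 for metallothioneins, 14 for DNA replication, 9 for QKI-linked genes and 3 for mRNA decay. They numbered 1 each for ZNF, osteoblast, stress granule, respiratory chain, hepatocyte, blood cell and long non-coding RNA lists, and the m7G and cap list had 1 higher and 1 lower. No member passed either way among ribosomal protein, NRF2, stress response, mitotic, glycolysis, snoRNA host and epithelial lists, nor over all genes among m7G and cap, blood cell and long non-coding RNA lists.

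Camera placed below other genes, besides cholesterol, p53 targets (4.53e-05), YAP and TAZ targets (5.13e-05), matrix (7.96e-05), SR proteins (1.27e-04), DNA replication (7.17e-04), unfolded protein response (8.05e-04), proteasome (9.89e-04), heat shock (0.00226), Hippo (0.00296), QKI-linked (0.00878), stress granule (0.0101), mRNA decay (0.0159) and mitotic genes (0.0394). It placed above them ribosomal proteins (0.00104), stress response (0.0187), ZNF genes (0.0244) and epithelial markers (0.0249). None of the 18 calls held: adjusted p = 0.653 with an estimated correlation for p53 targets, 0.807 for ZNF genes and 0.781 for the other 15 beside cholesterol. Lists that did not pass were interferon-stimulated genes (0.0547), snoRNA hosts and glycolysis (0.124 each), respiratory chain and NRF2 targets (0.209 each), blood cell markers (0.309), immediate-early mRNAs (0.335), long non-coding RNAs (0.51), osteoblast genes (0.757), and m7G and histone genes (0.938 each). Median and test differed in sign for mitotic, blood cell, long non-coding RNA and histone lists, and the ZNF median, 0.01 above that of all genes, was −0.01 with quantile normalisation.

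The median of all genes was −0.15, and 90.9% of genes lay below 0. Quantile normalisation, which removes such a shift, left 49 genes higher and 93 lower, and library totals 17 and 38; the named genes that passed kept their direction. The count was 77 and 175 without QKI7-WT replicate 1 or 2, and 16 and 118 without QKI7-dKH replicate 1 or 2. Of 67 named genes that passed, SUGCT, MYL2, HMGCS1 and THBS1 were the 4 that passed whichever library was left out.

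The remaining comparisons at 0 h set each add-back against sgQKI+EV. In QKI7-WT 11 genes passed, 8 higher and 3 lower, among them POP3 (1.28), the cytokine gene IL32 (0.90, adjusted p = 2.1e-04), LOC100506476 (0.69), COL8A1 (−0.58), the chemokine gene CXCL14 (−0.53) and ECM1 (−0.51). In QKI7-dKH 1590 genes passed, 1575 higher and 15 lower, with SNORD17 (1.13), CASC8 (1.10) and the keratin-associated KRTAP2-3 (1.09) at the upper end. The spliceosomal RNAs RNU1-1 (−1.15) and RNU2-1 (−1.0) and MAFA-AS1 (−0.91) were at the lower end. Across 37 small RNA rows the median in QKI7-dKH was −0.74, with 1 row higher and 5 lower. The median of all genes was 0.03 in the first (−0.013 without sgQKI+EV replicate 2, 0.077 without its replicate 1) and 0.19 in the second (0.134 to 0.24 with 1 library left out); with quantile normalisation 57 and 76 genes were higher and lower in the first, and 41 and 46 in the second. Without sgQKI+EV replicate 1 or 2 the first count was 5 or 2, and 5 without either QKI7-WT library. The second was 121 or 20 without sgQKI+EV replicate 1 or 2, and 34 or 1026 without QKI7-dKH replicate 1 or 2. IL32 passed whichever library was left out, and none of the 7 named genes of the second comparison did.

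Across the comparisons of sgQKI+EV with sgNS+EV and of QKI7-WT with QKI7-dKH at 0 h, which share no library, 8 genes passed in opposite directions, where 0.935 would be expected by chance. Among them COL3A1 and FHL1 were lower in targeted cells and higher in QKI7-WT than in QKI7-dKH, and FLJ23867, HIST1H2BK, PTBP2, SAA1 and TM4SF1 the reverse. SAA1 and TM4SF1 are named after their values were seen. Such a call does not show a return to the control level. By the means given above, COL3A1 was close in sgQKI+EV and QKI7-WT, both far below sgNS+EV, and lowest in QKI7-dKH. Another 9 genes passed in the same direction, where 6.39 would be expected. Across genes, which are not independent replicates, the changes correlated with Pearson r = −0.241 and Spearman −0.212; with 1 library left out Pearson r ranged from −0.305 to −0.048, the latter without QKI7-WT replicate 2. The count of 8 ranged from 0 to 5 when 1 library was left out, each of the 8 libraries moving it by more than 1.5 times.

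The third comparison asked which transcripts were lost by 8 h in control cells. CYR61, now CCN1, a matricellular immediate-early gene (chromosome 1, 85580761 to 85583962), fell from 217 ± 7.2 to 4.83 ± 0.53, a fold of 0.0266 (−5.23, SE 0.09, adjusted p = 6.2e-21). NFKBIA, the NF-κB inhibitor, fell too (−4.96), as did CTGF (−4.93), the HLH regulators ID1 (−4.91) and ID2 (−4.40), RPL22L1 (−4.72), IER3 (−4.57) and IER5 (−4.29). At the other end SNORD3B-1 (1.37), SCARNA16 (1.36), RNA5-8S5 (1.05), HIST1H4C (1.05), RN7SK (0.90), RHPN1 (0.85, adjusted p = 2.03e-06), P2RX6 (0.76) and OSBPL7 (0.73) rose. Of them 4 are small nuclear, nucleolar or ribosomal RNAs. Across 37 small RNA rows 5 rose and 2 fell, with a median of −0.51. In all, 11116 genes passed, 48 higher and 11068 lower, and 3186 changed at least 2-fold.

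All 33 immediate-early and ARE-containing mRNAs fell, with a median of −2.12, below that of all genes (difference −1.42, camera adjusted p = 1.09e-15; adjusted p = 0.249 with an estimated correlation). All 24 YAP and TAZ targets fell, such as FJX1 (−3.67) and ANKRD1 (−3.49), and 45 of 46 Hippo pathway genes, such as FRMD6 (−2.22) and TAOK1 (−1.94). Of 50 stress granule genes 48 fell, such as PUM2 (−2.61), DDX6 (−2.25) and EIF4E (−1.77), and of 60 mRNA decay genes 55 fell, such as TOB1 (−2.41), CNOT6L (−2.33) and ZFP36L2 (−2.27). All 37 mitotic genes fell, such as TTK (−1.72) and ASPM (−1.53), all 44 DNA replication genes, such as CCNE2 (−1.95), all 36 matrix genes, such as THBS1 (−1.84) and COL1A1 (−1.69), and all 7 osteoblast-lineage genes, such as TNFRSF11B (−2.06) and RUNX2 (−1.85). Of 28 p53 targets 25 fell, such as BBC3 (−3.00), GDF15 (−2.54) and BTG2 (−2.35), and of 30 interferon-stimulated genes 29, such as IFIT2 (−3.55) and IFIT3 (−2.82).

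Of 24 cholesterol genes 22 fell, such as INSIG1 (−2.02), and of 20 glycolysis genes 19, such as SLC2A1 (−2.31) and LDHA (−1.90). Of 22 unfolded protein response genes 18 fell, such as EIF2AK3 (−2.10), HERPUD1 (−1.97) and HSPA5 (−1.81), and of 32 NRF2 targets 25, such as GCLC (−1.63) and SLC7A11 (−1.43). In the stress response list 21 of 29 fell, such as DDIT4 (−3.71) and PPP1R15A (−2.20), and 1 rose. Of 30 heat shock genes 15 fell, such as DNAJB1 (−1.91) and HSF2 (−1.07), and 1 rose. Others that fell were 30 of 31 proteasome subunits, such as PSMD11 (−0.71), 37 of 38 SR proteins and hnRNPs, such as MBNL1 (−1.46), 16 of 18 m7G and cap genes, such as RNGTT and RNMT (−1.32 each), and 12 of 13 QKI-linked genes, such as CDKN1B (−3.53) and CCND1 (−1.14). METTL1, WDR4 and G3BP1 fell by 1.03, 0.95 and 0.77. Further falls were in 338 of 351 ZNF genes, such as ZNF830 (−2.83), with 1 rise, 16 of 21 snoRNA hosts, such as SNHG20 (−1.57), 13 of 17 histones, such as HIST1H4E (−1.55), with 1 rise, and 4 of 6 long non-coding RNAs, such as NORAD (−2.03) and TUG1 (−1.01), with 1 rise. Among markers of other cell types 4 of 5 blood cell, such as CORO1A (−0.74), 6 of 7 epithelial, such as CLDN4 (−1.80), and the 1 hepatocyte marker fell, as did 4 of 4 metallothionein and zinc export genes, such as SLC30A1 (−1.51).

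The smallest median falls were in 75 ribosomal protein mRNAs, of which 30 fell, such as RPL7A (−0.38) and RPLP0 (−0.34), and 76 respiratory chain mRNAs, of which 33 fell, such as NDUFC2 (−0.68) and SDHA (−0.65). Adjusted over the list alone these counts were 9 and 29, the stress response had 20 lower and QKI-linked genes 13, and the other lists gave the counts stated. Camera called 15 lists. Above other genes were ribosomal proteins (7.44e-17), respiratory chain (1.09e-15), heat shock (8.03e-06), snoRNA hosts and histones (0.0301 each). Below were immediate-early mRNAs, YAP and TAZ targets (1.59e-07), Hippo (5.17e-05), stress granule and mitotic genes (0.00137 each), matrix (0.0099), mRNA decay and DNA replication (0.0301 each), p53 targets (0.048) and ZNF genes (0.0489). With an estimated correlation none held; adjusted p = 0.89 with an estimated correlation for ZNF genes, 0.807 for matrix, mRNA decay and DNA replication, and 0.778 for the rest beside immediate-early mRNAs. Others gave 0.0702 for osteoblast genes, 0.0785 for blood cell markers, 0.0974 for QKI-linked genes, 0.127 for SR proteins, 0.248 for long non-coding RNAs, and 0.27 for stress response, interferon and proteasome lists. They gave 0.415 for m7G, 0.6 for NRF2, 0.708 for cholesterol and epithelial lists, 0.782 for unfolded protein response and 0.935 for glycolysis. Median relative to all genes and test differed in sign for DNA replication, SR proteins, cholesterol and unfolded protein response.

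Here the median of all genes was −0.70, so falls of long-lived mRNAs depend on the spike-in scale. Library totals moved it to −0.23, with 1616 genes higher and 6130 lower, and quantile normalisation to 0.05, with 4161 and 3381. With library totals the medians of ribosomal protein, respiratory chain, heat shock, NRF2, stress response, glycolysis, proteasome, snoRNA host and unfolded protein response lists, metallothioneins and the hepatocyte marker turned positive, as for ribosomal proteins, from −0.19 to 0.33; with quantile normalisation those of cholesterol, long non-coding RNA, histone and blood cell lists did so too. Relative to all genes, DNA replication went from 0.07 to −0.09 with quantile normalisation, SR proteins from 0.09 to −0.18, glycolysis from 0.27 to −0.13, unfolded protein response from 0.21 to −0.07, epithelial markers from 0.15 to −0.19 and metallothioneins from 0.33 to −0.06. Ribosomal proteins went from 0.51 to 0, mRNA decay went from −0.01 to 0.02 without ribosomal RNA, and long non-coding RNAs from 0.02 to −0.05. RPL7A, RPLP0, NDUFC2 and CORO1A changed sign under at least 1 of these scalings, and SCARNA16 and HIST1H4C rose under each. The count was between 10172 and 10896 with 1 library left out, and 120 of 130 named genes passed whichever it was.

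**Figure D2:**
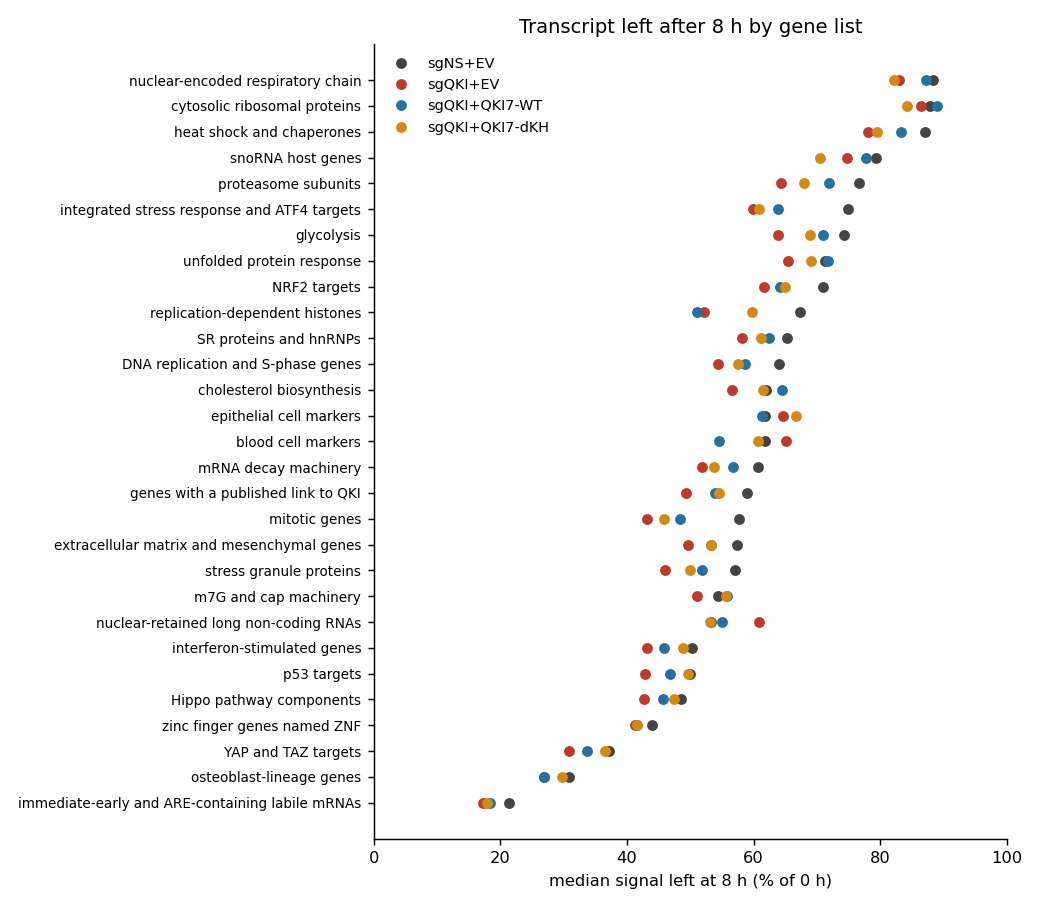
Median percent of the 0 h signal left at 8 h for 29 gene lists in the 4 genotypes, with 1 point per list and genotype, on the deposited spike-in scale. The immediate-early list had 21.4% left in sgNS+EV and 17.2% in sgQKI+EV, and ribosomal protein mRNAs 87.9% and 86.4%; with library totals in place of the spike-in the medians of ribosomal protein and respiratory chain lists were above 100% of 0 h.

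In the other genotypes the 8 h change was of the same kind. In sgQKI+EV 11404 genes passed, 53 higher and 11351 lower, in QKI7-dKH 11432, 61 and 11371, and in QKI7-WT 11351, 55 and 11296. In these genotypes ID1 changed by −5.50, −5.22 and −5.15 and CYR61 by −5.45, −5.44 and −5.79. CTGF changed by −5.37 in sgQKI+EV and −5.19 in QKI7-WT, and RPL22L1 by −5.05 in QKI7-dKH. The small Cajal body RNA SCARNA16 rose by 2.28, 2.79 and 2.04 and RNA5-8S5 by 2.09, 2.58 and 2.08. SNORA109 rose by 1.41 in sgQKI+EV and 2.48 in QKI7-WT, and SNORD3A by 2.22 in QKI7-dKH. The median 8 h change of 37 small RNA rows was −0.67, 1.42 and 0.81 in these genotypes. Whether such rows of polyA libraries measure RNA amount was not tested. Ribosomal RNA18S5 was 72330 and 27730 in the sgQKI+EV libraries at 0 h. METTL1, WDR4 and G3BP1 fell in each genotype on the deposited scale, and WDR4 reversed with quantile normalisation in these 3 genotypes (0.05, 0.17 and 0.21), as did METTL1 in sgQKI+EV (0.07). Quantile normalisation gave 4531 higher and 3743 lower in sgQKI+EV, 4291 and 3586 in QKI7-dKH, and 4274 and 3600 in QKI7-WT. Median half-life over all genes was 10.3 h in sgNS+EV (10.1 to 10.7 with 1 library left out), 8.83 h in sgQKI+EV (8.26 to 9.45), 9.53 h in QKI7-dKH (8.9 to 10.3) and 9.34 h in QKI7-WT (8.76 to 10). Without the added constant, median changes from 0 h to 4 h were −0.336, −0.423, −0.519 and −0.248 in these genotypes. From 4 h to 8 h they were −0.434, −0.493, −0.333 and −0.597. By these medians loss was uneven between the intervals and the genotype order differed, which was not tested. Medians of the 2 replicates of a group differed by up to 0.15. With the added constant, the QKI7-WT change from 0 h to 4 h was −0.228, and −0.31 without its 4 h replicate 1. These half-lives and their order rest on the spike-in scale: the median 8 h changes of −0.70, −0.82, −0.77 and −0.77 in these genotypes were −0.23, −0.26, −0.22 and −0.28 with library totals, and above 0 with quantile normalisation. Across genes the 8 h changes correlated with r = 0.939 between sgNS+EV and sgQKI+EV and 0.962 between QKI7-WT and QKI7-dKH.

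The fourth comparison asked whether transcripts were lost faster in QKI-targeted cells. HSPA5, the endoplasmic reticulum chaperone BiP (chromosome 9, 125234853 to 125241330), fell from 346 ± 19 to 98.0 ± 3.8 in sgNS+EV and from 352 ± 3.5 to 54.8 ± 1.3 in sgQKI+EV. The decay difference was −0.85 (SE 0.10, adjusted p = 5.03e-04), and half-lives were 4.40 h and 2.98 h. AMOTL2, an angiomotin of the Hippo pathway (chromosome 3, 134355874 to 134375479), fell from 64.7 ± 0.99 to 22.5 ± 0.67 and from 74.4 ± 0.73 to 15.3 ± 0.48 (−0.72, SE 0.10). KPNA2, an importin alpha of cycling cells (chromosome 17, 68035519 to 68046842), fell from 921 ± 48 to 422 ± 28 and from 902 ± 18 to 264 ± 12 (−0.65, SE 0.11). POP3 was the 1 gene with a smaller fall in sgQKI+EV, at 11.3 ± 1.8 to 3.12 ± 0.96 in control and 3.68 ± 0.4 to 3.73 ± 1.6 in targeted cells (1.57, SE 0.35). In all, 85 genes passed, 84 of them with the larger fall in targeted cells, and 22 differed at least 1.5-fold.

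Mitotic genes were the list with most members past the test. Of 37, 12 fell further in targeted cells and none less, and 34 adjusted over the list alone. CKAP2L, a spindle protein gene, and CENPA, the centromeric histone, gave −0.57, the kinase PLK1 (chromosome 16, 23677656 to 23690367) −0.54 and the kinesin KIF20A −0.51, with half-lives in control and targeted cells of 9.18 and 5.49 h, 7.41 and 4.81 h, 10.1 and 5.96 h, and 11.6 and 6.63 h. The list's median of −0.42 lay below that of all genes (difference −0.28, camera adjusted p = 1.7e-26; adjusted p = 0.197 with an estimated correlation). The fry test, which sets the list against no change and not against other genes, gave adjusted p = 0.00199. The difference remained negative with quantile normalisation, at −0.23. Of 44 DNA replication genes PCNA (−0.53) fell further, and 18 over the list alone. The histones HIST1H4H (−0.95), HIST1H2BD (−0.62) and HIST2H2BE (−0.56) fell further among 17, while over the list alone 6 fell further and 1 less.

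Of 33 immediate-early and ARE-containing mRNAs 4 fell further, and 11 over the list alone: ID3 (−0.87), BTG2 (−0.64), PLK2 (−0.62) and ZFP36L1 (−0.63), itself a decay factor for ARE-containing mRNAs. The kinases PIM3 (−0.66) and PIM1 (−0.65) and the growth factor BMP4 (−0.74) were among the largest differences. YAP and TAZ targets included ANKRD1 (−0.61) and AMOTL2 (9 over the list alone, of 24), p53 targets PLK2 and BTG2 (3 of 28), matrix genes THBS1 (−0.47) and FBN2 (−0.44) (4 of 36). Single members were TXNRD1 (−0.57) of NRF2 targets (3 over the list alone), DNAJB1 (−0.59) of heat shock genes (1), DDX3X (−0.46) of stress granule genes (1), AMOTL2 of Hippo genes (3), ZFP36L1 of mRNA decay genes (3) and HSPA5 of the unfolded protein response (2). Over the list alone 5 of 24 cholesterol genes fell further. None passed over all genes in the stress response, proteasome and long non-coding RNA lists, with 10, 4 and 2 lower over the list alone. None passed either way among ribosomal protein, respiratory chain, m7G, QKI-linked, osteoblast, interferon, glycolysis, snoRNA host, SR protein, ZNF, metallothionein, blood cell, epithelial and hepatocyte lists. METTL1, WDR4 and G3BP1 gave 0.09, −0.02 and −0.24, with adjusted p of 0.855, 0.962 and 0.216.

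**Figure D3:**
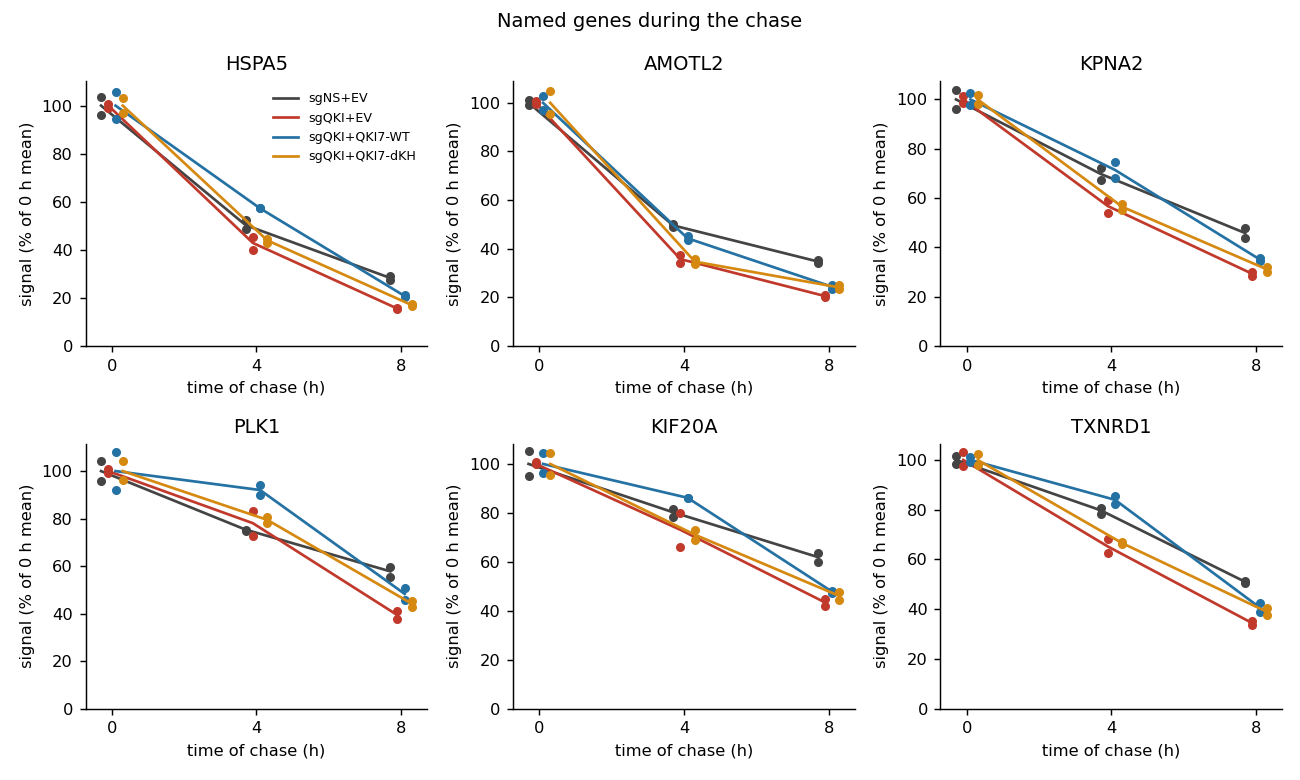
Signal of HSPA5, AMOTL2, KPNA2, PLK1, KIF20A and TXNRD1 as percent of the 0 h group mean against hours of chase, with 1 point per library and lines through group means in the 4 genotypes. The log2 decay difference of sgQKI+EV against sgNS+EV ran from −0.85 for HSPA5 to −0.51 for KIF20A, and the PLK1 difference at 4 h was 0.05, opposite to that at 8 h.

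Camera called 16 lists for this difference. Further loss than other genes was seen, besides mitotic genes, for DNA replication (9.45e-07), stress granule (4e-05), proteasome (5.41e-05), stress response (9.66e-05), YAP and TAZ targets (1.35e-04), immediate-early (0.00777), mRNA decay (0.0114), cholesterol (0.0125), NRF2 (0.0288), Hippo (0.0405), p53 (0.0446), matrix (0.0452) and QKI-linked genes (0.0463). Less loss was seen for ribosomal proteins (1.42e-04) and ZNF genes (0.0361). With an estimated correlation none held, with adjusted p = 0.736 for ribosomal proteins, mRNA decay and NRF2 targets, 0.759 for Hippo and matrix, 0.79 for ZNF and 0.718 for the other 9 beside mitotic genes. Others gave 0.0542 for heat shock, 0.0558 for SR proteins, 0.0725 for histones and blood cell markers, 0.0989 for epithelial markers, 0.102 for glycolysis, 0.197 for unfolded protein response, and 0.215 for snoRNA hosts and long non-coding RNAs. They gave 0.391 for interferon-stimulated, 0.575 for respiratory chain, 0.75 for m7G and 0.929 for osteoblast genes. Median and test differed in sign for unfolded protein response and osteoblast genes, and median and mean for epithelial markers and long non-coding RNAs. With quantile normalisation the matrix median went from −0.01 to 0.01 relative to all genes, ZNF from 0.03 to −0.02, SR proteins from −0.02 to 0.01 and blood cell markers from 0.09 to −0.01.

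The median of all genes was −0.14, and 79% of genes lay below 0. With quantile normalisation 12 genes fell less and 54 fell further, and with library totals 2 and 52. Leaving out a library also costs power. In the simulations of this difference, recovery at a log2 change of 0.5 was 41.8% with all libraries and 29.9% with 1 left out. The count of 85 rested on every library: it was 2 and 11 without sgNS+EV 0 h replicate 1 or 2, 8 and 1 without sgNS+EV 8 h replicate 1 or 2, 2 and 7 without sgQKI+EV 0 h replicate 1 or 2, and 10 and 2 without sgQKI+EV 8 h replicate 1 or 2. HSPA5 was the 1 of 26 named genes that passed whichever library was left out, at an adjusted p of at most 0.0112. AMOTL2 was lost without sgNS+EV 8 h replicate 2 alone (adjusted p = 0.0549). KPNA2 was lost without sgNS+EV 0 h replicate 1 (0.0825), sgNS+EV 8 h replicate 2 (0.0984), sgQKI+EV 0 h replicate 1 (0.119) or sgQKI+EV 8 h replicate 2 (0.0738). POP3 was lost without any 1 of the 8, at adjusted p from 0.0682 to 0.223, and PLK1 likewise, from 0.0773 to 0.227. Over the first 4 h, ID3 (0.02), DNAJB1 (0.00) and PLK1 (0.05) did not show the 8 h direction.

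The fifth comparison asked whether intact QKI7 changed loss relative to QKI7 without the KH domain. HSPA5 gave 0.29, KPNA2 0.18, PLK1 0.13, TXNRD1 0.05 and AMOTL2 0.02, each with an adjusted p of 1, and QKI itself −0.12. Their 8 h changes in QKI7-dKH and QKI7-WT were −2.54 and −2.25 for HSPA5, −1.69 and −1.51 for KPNA2, −1.17 and −1.04 for PLK1, −1.35 and −1.29 for TXNRD1, and −2.00 and −1.98 for AMOTL2. In limma 0 genes passed, and 120 had an unadjusted p under 0.05, where 627.4 would be expected by chance. A count so far below chance means that the p-values ran high for this comparison. The 0 therefore does not show that loss was equal. The spread was pooled over all groups. Replicate differences had an SD of 0.31 log2 in QKI7-WT at 4 h, against 0.12 to 0.21 in the groups compared here. The smallest p-values, which did not pass, were of SLC25A20 (−0.73), PILRB (0.76), YTHDF3-AS1 (−1.05), ST3GAL4-AS1 (−0.94) and MILR1 (−0.80). The decay differences of the add-backs against sgQKI+EV also gave 0 genes each. Unadjusted p was under 0.05 for 344 genes in QKI7-WT and 323 in QKI7-dKH, again fewer than expected by chance. HSPA5 gave 0.41 and 0.13 in these, KPNA2 0.26 and 0.08, and PLK1 0.29 and 0.16. Without QKI7-dKH 0 h replicate 1, 22 genes fell less in QKI7-dKH than in sgQKI+EV.

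In each list no member passed for this difference, over all genes or over the list alone. Camera placed above other genes ribosomal proteins (0.09, adjusted p = 5.44e-08), respiratory chain (0.08, 2.74e-05), cholesterol (0.09, 6.68e-05), mitotic (0.06, 5.32e-04), heat shock (0.07, 8.63e-04), proteasome (0.05, 0.00539), matrix (0.0239) and snoRNA host genes (0.0377), and below them interferon-stimulated genes (−0.07, 8.63e-04), the medians being in log2. None of the 9 held, at adjusted p = 0.948 with an estimated correlation. The fry test, of each list against no change, gave 0.988 for each. The other lists ranged from 0.0532 for NRF2 targets, 0.0572 for YAP and TAZ targets, 0.0884 for DNA replication, 0.103 for stress response, 0.133 for epithelial, 0.137 for SR proteins, 0.157 for stress granule, 0.184 for Hippo and long non-coding RNAs, 0.294 for mRNA decay and 0.315 for glycolysis. Higher still were 0.392 for blood cell, 0.541 for osteoblast, 0.595 for immediate-early, 0.719 for histone, 0.72 for QKI-linked, 0.75 for ZNF, 0.836 for m7G, and 0.891 for p53 and unfolded protein response lists. Signs of median, mean or test differed for immediate-early, histone, QKI-linked and m7G genes. With quantile normalisation, relative to all genes, the ribosomal protein median went from 0.09 to 0, respiratory chain from 0.08 to 0.01, heat shock from 0.07 to 0.01 and proteasome from 0.05 to 0, and stress granule, SR protein, glycolysis and p53 medians changed sign within 0.04 of 0.

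**Figure D4:**
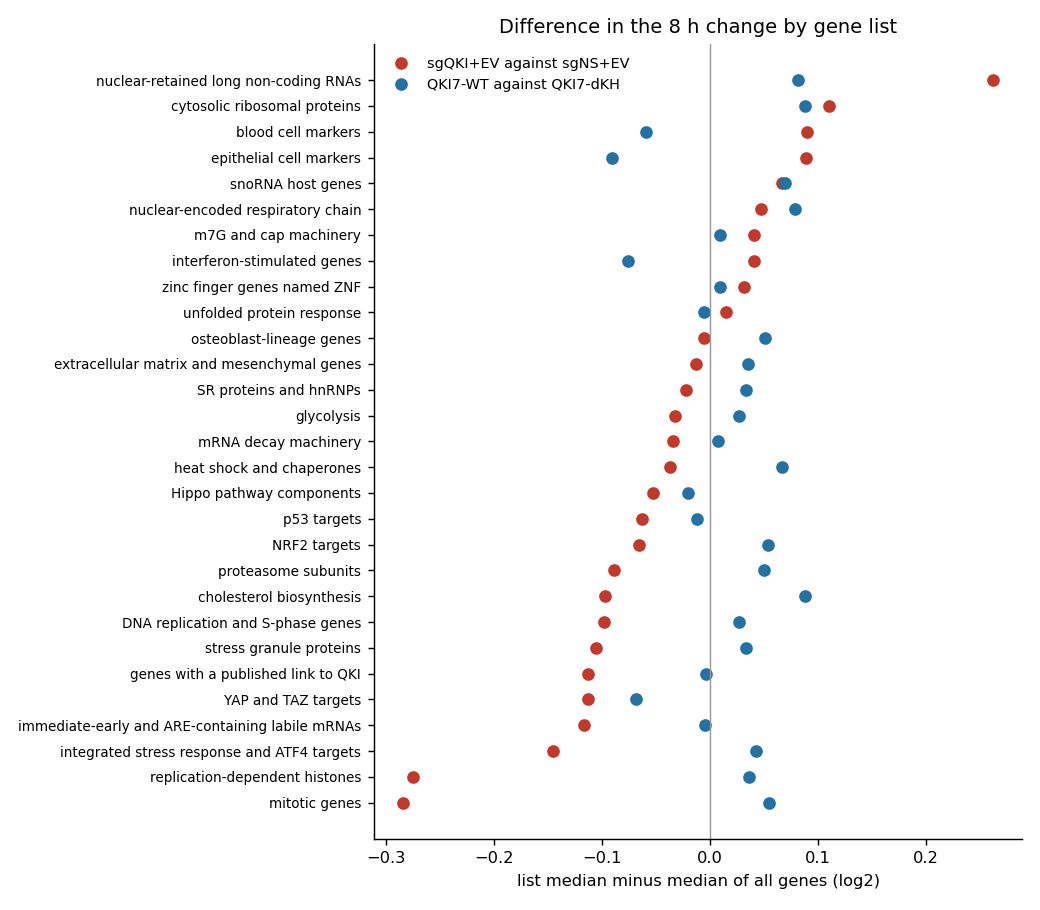
Median log2 decay difference of each of the 29 gene lists minus that of all genes, with 1 point per list for sgQKI+EV against sgNS+EV and 1 for QKI7-WT against QKI7-dKH. Mitotic genes lay at −0.28 in the first and 0.06 in the second; matrix, ZNF, SR protein and blood cell lists changed sign with quantile normalisation in the first, and stress granule, SR protein, glycolysis and p53 lists in the second.

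Set side by side, 63 of the 85 genes with a different loss in targeted cells (74.1%) had the opposite sign in QKI7-WT against QKI7-dKH, as did 53.4% of all genes. These signs were taken relative to the median of all genes in each comparison. Across genes the decay differences correlated with r = −0.0886, a value whose sign rests on 1 library: with 1 left out it ranged from −0.177 to 0.031, both reached without a QKI7-WT 0 h library. Of the 195 genes that differed in targeted cells at 0 h, 157 also passed in the same direction at 8 h, where 58.5 would be expected by chance, and TXNRD1 passed in the opposite direction, higher at 0 h and lower at 8 h.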

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

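Tests chosen only after the result was seen were the covariate test and the early-decay test of the 4 h pattern, both tests of the QKI7-dKH level, and the scale-factor and add-back tests of the mitotic pattern; the others were chosen before their results were known.

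The test of the difference in loss itself gave 85 genes for sgQKI+EV against sgNS+EV from 0 h to 8 h. Log2 values of named genes included 1.57 for POP3, −0.95 for HIST1H4H, −0.87 for ID3, −0.85 for HSPA5, −0.74 for BMP4, −0.72 for AMOTL2, −0.66 for PIM3, −0.65 for KPNA2 and PIM1, −0.64 for BTG2, −0.63 for ZFP36L1, −0.62 for PLK2 and HIST1H2BD, −0.61 for ANKRD1, −0.59 for DNAJB1, −0.57 for TXNRD1, CKAP2L and CENPA, −0.56 for HIST2H2BE, −0.54 for PLK1, −0.53 for PCNA, −0.51 for KIF20A, −0.47 for THBS1, −0.46 for DDX3X and −0.44 for FBN2. The count was between 1 and 11 with any of the 8 libraries left out, and HSPA5 was the 1 named gene that passed each time. From 0 h to 4 h the same test gave 1341 genes for sgQKI+EV against sgNS+EV, 2012 for QKI7-WT against QKI7-dKH and 1 for QKI7-WT against sgQKI+EV. The count of 2012 was 0 with quantile normalisation, with library totals or without QKI7-WT 4 h replicate 1. With the spike-in axis as a covariate it was 3929, and the count of 1 was 1893. For the 2012 genes the median size went from 0.419 to 0.337 and the median SE from 0.119 to 0.107. The differences shrank in part, so the axis does not account for the whole of them.

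Mitotic genes fell further from 0 h to 8 h in sgQKI+EV than in sgNS+EV, with members' median falls of −1.21 and −0.79, and −1.12 in QKI7-dKH and −1.04 in QKI7-WT. A bias shared with the spike-in RNAs, transcript length, GC content or abundance, and a single library were each argued against as the whole cause. The list stayed below its reference in each of these tests. Its median lay −0.31 from that of all genes with the spike-in axis as a covariate, and −0.24 at the least with 1 library left out. From 20 matched genes per member it lay −0.21. The 95% interval of that value, −0.247 to −0.188, came from resampling list members. It measures spread among genes of the same libraries and not between libraries. With quantile normalisation the median lay −0.23 from that of all genes. That value could not test one scale factor per library, which moves the list and all genes nearly alike. For loss of a QKI7 function that needs the KH domain, QKI7-WT against QKI7-dKH gave 0.055, below the 0.142 set for that explanation. These data hold no QKI7 protein values, and a weak add-back would also give a small value, so 0.055 does not decide it. Against sgQKI+EV the list gave 0.113 in QKI7-WT and 0.0406 in QKI7-dKH. The explanation stays open, in whole or in part. A slower cell cycle, an effect of the guide on other genes and a QKI isoform other than QKI7 may each contribute and were not tested, and the camera call was lost with an estimated correlation (adjusted p = 0.197).

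More genes differed in loss between sgQKI+EV and sgNS+EV over the first 4 h (1341) than over 8 h (85), and the 4 h count was 2446 with quantile normalisation, 4852 with library totals, 3909 with totals without ribosomal RNA and 3303 without QKI7-WT 4 h replicate 1. With the spike-in axis as a covariate 1 gene passed; the called genes' median size went from 0.552 to 0.298 and their SE from 0.153 to 0.13, so the call ended because the differences shrank. In the 16 libraries outside this comparison, a gene's slope on the spike-in axis correlated with its 4 h difference across genes with r = −0.798. Both values go with a library bias that also moved the spike-in RNAs, mainly 1 of them (loading 0.783). The slope used differences within groups, and the axis differed most between the QKI7-WT 4 h libraries (0.438 and −0.162). That slope therefore rests largely on this pair. An early difference in decay stays open, since 4 h and 8 h differences made from separate 0 h libraries correlated across genes with r = 0.108, between the bounds set for and against it.

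Most genes had a higher signal in QKI7-dKH than in sgQKI+EV at 0 h, 1575 of the 1590 that passed. After scaling to the total without ribosomal RNA 16 genes were higher, which is consistent with one scale factor per library. More RNA per cell in QKI7-dKH cannot be told apart from such a factor, because how the spike-in was added is not known. The median difference was 0.19, 0.11 and 0.25 at 0, 4 and 8 h, so its lowest, 0.11, was positive. The same shift enters each comparison of QKI7-WT with QKI7-dKH at 0 h, where the named cholesterol gene HMGCS1 had its highest mean in QKI7-dKH.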

How the results depend on the processing

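Scaling to library totals without ribosomal RNA, the spike-in axis as a covariate and the fit without 4 h libraries were chosen after seeing the data. No filter removed a gene, so that alternative shows nothing; methods that need counts were not run. With 1 library left out, the lone sample of its group is assumed to vary like the other groups. Depth is unknown, so its limits could not be tested. Where a cause is not given, the cause was not tested.

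Counts at 0 h for sgQKI+EV against sgNS+EV (195), QKI7-WT against QKI7-dKH (471), QKI7-WT against sgQKI+EV (11) and QKI7-dKH against sgQKI+EV (1590) were, in this order, 776, 142, 133 and 87 with quantile normalisation, 1032, 55, 92 and 47 with library totals, and 389, 88, 69 and 43 with library totals without ribosomal RNA. They were 1328, 265, 41 and 3736 from the compared groups alone, 627, 2959, 71 and 4600 with the spike-in axis, 464, 1588, 26 and 3647 without the 4 h libraries, and 5, 3, 1 and 10 with a 2-fold limit, which by construction can only lower a count. With 1 library left out they ranged from 25 to 99, 16 to 175, 2 to 5 and 20 to 1026.

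Counts of the 8 h change ranged with 1 library left out from 10172 to 10896 in sgNS+EV, 10628 to 11325 in sgQKI+EV, 10381 to 11435 in QKI7-dKH and 10415 to 11480 in QKI7-WT. A 2-fold limit gave 3186, 4464, 3890 and 3970, and 4 h in place of 8 h gave 5714 in QKI7-WT. The decay difference of sgQKI+EV against sgNS+EV (85) was 54 with library totals, 1373 from the compared groups alone, 1341 at 4 h, 1005 with the spike-in axis, 437 without the 4 h libraries, 22 with a 1.5-fold limit, and 1 to 11 with 1 library left out. The decay difference of QKI7-WT against QKI7-dKH was 2012 at 4 h, that of QKI7-WT against sgQKI+EV 1 at 4 h, and that of QKI7-dKH against sgQKI+EV 44 from the compared groups alone and 31 with the spike-in axis. These were 0 to 0, 0 to 0 and 0 to 22 with 1 library left out.

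Opposite calls at 0 h (8) were 36 with quantile normalisation, 21 with library totals, 53 from the compared groups alone, 19 without ribosomal RNA, 58 with the spike-in axis, 28 without the 4 h libraries, and 0 to 5 with 1 library left out. Opposite calls in decay were 559 at 4 h, and 0 to 0 with 1 library left out. The 15 lists called for the 8 h change in sgNS+EV were 8 with library totals and 7 at 4 h, and the 9 called for the decay of QKI7-WT against QKI7-dKH were 2 with quantile normalisation. With 4 h in place of 8 h, camera called some lists in the other direction: snoRNA hosts for the change in sgNS+EV (0.0371) and for the decay of QKI7-WT against QKI7-dKH (0.00465), and, for the decay of sgQKI+EV against sgNS+EV, proteasome and ZNF genes (0.00443 each). For that decay, glycolysis (0.00443) and histones (0.0121), not called at 8 h, were called as falling less at 4 h. These 4 h list calls used the preset correlation of 0.01 and were not repeated with an estimated one, with which none of the 8 h calls held. A pseudocount of 0.1 kept each count within 1.5 times, as 162, 418, 8 and 1465 at 0 h and 111 for the decay difference.

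A replicate block gave 218, 564, 9 and 1871 genes at 0 h and 109 for the decay difference of sgQKI+EV against sgNS+EV, and kept the direction and call of 336 of 338 named results. Replicate numbers were checked as pairs: of 66 pairs of groups 21 had a correlation of replicate differences over 0.1, from −0.42 to 0.48, so the numbers were not taken to mark shared batches.

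For named results, direction was compared only where a value passed in either fit. By that rule call and direction stayed the same in 327 with a pseudocount of 0.1 and 329 with the spike-in axis. They stayed in 334 without the 4 h libraries and 298 from the compared groups alone. The counts were 263 and 248 with library totals without and with ribosomal RNA, and 254 with quantile normalisation. A sign change between values that did not pass was not counted as a reversal. QKI in QKI7-WT against QKI7-dKH at 0 h was such a case, going from 0.11 to −0.08 without QKI7-WT 0 h replicate 1. With 1 library left out 1018 of the values kept their call, 521 lost it, 1 gained one and 0 reversed. Named genes that reversed in the 8 h change of sgNS+EV did so with quantile normalisation for NDUFC2 (0.16), NDUFA10 (0.13), DNAJB4 (0.01), MT1X (0.19), MT1E (0.09), PSMA5 (0.11), PVT1 (0.16), FTX (0.01), CORO1A (0.18), CD34 (0.11), MYB (0.22), CD33 (0.45), EPCAM (0.36) and SERPINA1 (0.24). With library totals, then without ribosomal RNA, RPL7A gave 0.14 and 0.07, RPLP0 0.18 and 0.11, RPL3 0.18 and 0.11, RPL4 0.18 and 0.12, MT1X 0.12 and 0.06, MT1E 0.16 and 0.09, MT2A 0.20 and 0.14, SERPINA1 0.31 and 0.24, and PSMA5 0.01 with totals. These scalings raise 8 h values relative to 0 h by construction. At 4 h RNA5-8S5 gave −0.58, HIST1H4C −0.06, RN7SK −0.02 and EPCAM 0.03. With quantile normalisation METTL1 gave 0.07 in sgQKI+EV and WDR4 0.05 in sgQKI+EV, 0.17 in QKI7-dKH and 0.21 in QKI7-WT. The 4 h decay difference of sgQKI+EV against sgNS+EV gave 0.02 for ID3, 0.00 for DNAJB1 and 0.05 for PLK1, and that of QKI7-WT against QKI7-dKH 0.65 for QKI.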

Other observations

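Tests of QKI sites were chosen before their results were seen; the correlation of the spike-in axis with the samples was examined after the data were seen.

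Loss differed widely between gene groups. In sgNS+EV the median half-life was 3.6 h for immediate-early and ARE-containing mRNAs, 4.71 h for osteoblast-lineage genes, 5.61 h for YAP and TAZ targets and 6.74 h for zinc finger genes. It was 20.9 h for proteasome subunits, 40.3 h for heat shock genes, 43 h for ribosomal protein mRNAs and 45.1 h for the respiratory chain. Half-lives used 0 h and 8 h alone, and loss was not even between them for these 4 lists. At 4 h and 8 h they had 85% and 76.7% left, 86.9% and 87.1%, 90.7% and 87.9%, and 85.1% and 88.4%, in this order. All these half-lives depend on the spike-in scale: with library totals the median 8 h change in sgNS+EV went from −0.99 to −0.55 for zinc finger genes, from −0.79 to −0.27 for mitotic genes and from −0.41 to 0.10 for stress response genes. In sgQKI+EV the immediate-early list had 3.15 h, mitotic genes 6.58 h against 10.1 h in control cells, DNA replication genes 9.11 h against 12.4 h, and stress response genes 10.8 h against 19.2 h. Mitotic genes had 7.12 h in QKI7-dKH and 7.63 h in QKI7-WT. Among single genes, NFKBIA had 1.44, 1.41, 1.46 and 1.43 h and CYR61 1.46, 1.39, 1.41 and 1.3 h in sgNS+EV, sgQKI+EV, QKI7-dKH and QKI7-WT. BMP4 had 9.23, 4.95, 5.50 and 5.53 h, and TXNRD1 8.23, 5.18, 5.91 and 6.15 h. These half-lives carry no test of their own; the decay differences do.

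Levels at 8 h gave a further view of COL3A1, FHL1, PTBP2 and FLJ23867. These genes, among the 8 with opposite calls at 0 h, had opposite calls again at 8 h, where 15 genes did so and 3.78 would be expected by chance; IGFBP7, CCL2 and SERPINB7 were among the others, named after their values were seen. At 8 h 244 genes passed in the same direction, where 206 would be expected. Signs were also taken relative to the median of all genes in each comparison. By that measure 58.3% of the genes that differed in targeted cells had the opposite sign, as did 57.6% of all genes. Before that centring, 86.9% of genes lay below 0 in sgQKI+EV against sgNS+EV at 8 h, and 90% in QKI7-WT against QKI7-dKH. QKI itself changed by −0.05 over the first 4 h in sgNS+EV (adjusted p = 0.79) and had fallen by 1.03 in sgQKI+EV and by 1.02 in QKI7-dKH, with −0.37 in QKI7-WT. The 4 h difference in loss for QKI was −0.99 (SE 0.20, adjusted p = 0.0347) for sgQKI+EV against sgNS+EV, and −0.49 (SE 0.11, adjusted p = 0.186) with the spike-in axis as a covariate. For QKI7-WT against QKI7-dKH it was 0.65 (adjusted p = 0.0407), and 0.28 (adjusted p = 0.0445) with the axis. That call was lost with quantile normalisation, with either scaling to totals and without QKI7-WT 4 h replicate 1, where 0 genes passed; QKI was 50.53 in that library and 32.8 in its replicate. The slope of QKI on that axis lay at the 98.9th percentile of genes. Of 37 small RNA rows, 5 rose from 0 h to 8 h in sgNS+EV, 7 in sgQKI+EV, 29 in QKI7-dKH and 13 in QKI7-WT. Their median changes were −0.51, −0.67, 1.42 and 0.81 in this order. None of the 37 passed in any of the 4 decay differences, and the rows were not tested as a group.

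The spike-in axis followed a minor component of the libraries. Over 24 libraries it correlated with the third principal component of the endogenous genes, which carried 2.98% of the variance, with Pearson r = 0.787 (permutation p = 1e-05, the smallest that 100000 permutations can give) and Spearman rho = 0.728 (permutation p = 7e-05). The third was the closest of 4 components compared, and these p-values do not allow for that choice; the first, with 86.4% of the variance, gave 0.428. Without the 2 libraries farthest from the median r was 0.643, and within groups it was 0.967. Across 11333 genes, which are not independent replicates, a gene's slope on the axis had a Spearman correlation of −0.738 with GC content, 0.322 with 3′ UTR length and 0.282 with transcript length. A candidate explanation is a GC-dependent library bias shared by spike-in and endogenous RNA. The 4 h difference of sgQKI+EV against sgNS+EV goes with it, since 1 gene was left with the spike-in axis as a covariate. That difference also correlated across genes with the slope in the 16 libraries outside the comparison (r = −0.798). This slope rests largely on the QKI7-WT 4 h pair.

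A hypothesis of direct binding was tested: that transcripts with a QKI recognition site in the 3′ UTR change together in targeted cells. Genes with a site (3779) were compared with genes without one (7425) within 20 classes of 3′ UTR length, with 10000 permutations. At 0 h in sgQKI+EV against sgNS+EV the median difference was 0.0083 log2 (permutation p = 0.0015, adjusted p = 0.004), for the decay difference −0.0079 (permutation p = 0.0027, adjusted p = 0.004), and at 0 h in QKI7-WT against QKI7-dKH 0.00049 (permutation p = 0.62). All 3 were smaller than the 0.03 set beforehand as the size that would speak against a broad effect. A site was any ACTAAC or ACTAAT in the annotated 3′ UTR. Genes that QKI does not bind may be included, which would dilute an effect on bound ones. The permutations treated genes as independent and matched 3′ UTR length but not GC content. Direct binding may still act on single transcripts such as HSPA5, which was not tested.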
